A study of Mus musculus with 8 samples.

How the data were processed

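The series holds 8 RNA sequencing libraries of crypts, the glands of the intestinal epithelium, from wild-type C57BL/6 mice on day 5. Per the labels, 4 libraries belong to mice given dextran sulfate sodium (DSS), a polymer that injures the gut lining and is used to induce colitis. The other 4 carry DSS with CA, which the series title gives as cholic acid, a primary bile acid; this group is called DSS_CA here. Per the labels' protocols, RNA was extracted with an RNeasy Micro kit and 200 ng of total RNA went into each TruSeq Stranded Total RNA library. The labels give neither the gut segment, nor the route or dose of either compound, nor whether the replicates are separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

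Each library came as one table of 34745 Ensembl genes with a raw count and an FPKM value per gene, per the file headers. HISAT2, StringTie and the builds GRCm38 and mm10 are named without versions, per the submitters' processing notes. The tool that made the deposited count column, its annotation and its strand setting are not given in the sources used here. The deposited FPKM values, per the file headers, equalled the count divided by a fixed gene length and by the library's total count. The length implied was the same in every library within 1% for 17718 of the 17718 genes with a count in 2 or more libraries. No table entry named anything other than a gene. Of the gene identifiers, 34344 were found in GENCODE release M21, and the 401 others took at most 0.106% of the counts of a library. Coordinates are those of the deposited tables, on GRCm38 (mm10).

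Total counts lay between 13334012 and 17973196 per library. Genes were tested where the deposited FPKM reached at least 1 in at least 4 of the 8 libraries, which left 9913 genes, of which 9407 were protein coding. Counts were compared between the groups with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with TMM scaling and the group as the only term. The tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and the threshold was an adjusted p of 0.05. Log2 fold changes are DSS_CA against DSS. Their standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic of the test. It is therefore derived from the test and is not a separate measure of precision. Levels are CPM scaled by TMM, given as mean and SD with n = 4 per group. The common biological coefficient of variation was 0.416. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

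Gene lists were compared as groups with the camera test of limma at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. These settings gave unlike p-values even where the estimate lay near the preset. For T and NK cells the estimate was 0.00469, and the camera p was 3.23e-30 at the preset and 2.30e-05 at the estimate. The very small p-values at the preset correlation thus depend on that setting. A list was tested with at least 5 measured members, and p-values were adjusted over the 31 lists tested. The 39 lists covered stem, injury-induced, secretory and absorptive epithelial cells, Wnt and Notch signalling, proliferation, energy, lipid, bile acid and xenobiotic metabolism, stress and immune responses, barrier genes, segment markers and other cell types. Of their 672 members, 668 were matched by symbol, 2 by an older symbol, and 2 were not matched. Members were also counted after adjustment over the list alone. Shares of counts were compared with exact two-sided permutation tests over the 70 assignments of 8 libraries to 4 and 4.

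The design, the lists, the test settings and the rule for naming genes were chosen before the data were examined. The rule named the genes past the threshold in each direction, up to 12, with non-overlapping groups, a mean of at least 2 in the higher group and an assigned symbol. It also named up to 4 members past the threshold in each list, or, in lists without any, the 2 members with the smallest p, and 19 fixed genes whatever their values. Some of the genes it named are not reported here. Members of the lists named beyond that rule were chosen after their values were seen. The design allowed for normalized values or for counts, and the branch for counts was used because the tables held them. The filter on deposited values was read as a filter on FPKM.

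The procedure was tested on simulated data for this comparison, with counts drawn for the 9913 genes and 200 genes changed by known folds. At folds of 2, 4 and 8, edgeR recovered 1.49%, 76.1% and 97% of the changed genes, with 4 unchanged genes called, and camera called 0 of 20 unchanged lists. The simulated genes were drawn independently of each other and the unchanged lists at random. The 0 of 20 therefore does not show how often camera calls unchanged lists whose genes are correlated. DESeq2 1.42.0 recovered 13.4%, 94% and 97%, with 34 unchanged genes called. Changes below about 4-fold were therefore often out of reach of the gene-level test.

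The alternatives chosen beforehand were limma on log2(FPKM + pseudocount) with pseudocounts of 1, 0.1 and 0.5, no filter, a stricter filter at FPKM 5, and other scalings. They also included limma voom with and without library quality weights, robust edgeR, the DESeq2 Wald test, a replicate block, an estimated correlation for the lists, and leaving out each library in turn. Added after the data were seen were the filterByExpr filter of edgeR, an offset for the trend of each library with gene length (loess span 0.5), and leaving out the 3 libraries with the shortest counted genes. Enrichment over KEGG terms was added after the data were seen as well. The counts of any pair of libraries differed by more than sampling noise, with a chi-square of at least 25 per degree of freedom. Each library was therefore counted as 1 sample. Separate preparations from 1 animal could differ as much, so this does not show that the samples are independent. The closest pair was DSS_CA 2 and DSS_CA 4, at 25.0, and the next was DSS_CA 1 and DSS_CA 4, at 62.7. Near-identical paralogs can share reads, so the values of Apol9a and Apol9b, Acot1 and Acot2, Gsta1, Lyz1 and the defensins Defa24 and Gm15284 are uncertain one by one.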

Results

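Crypts of wild-type C57BL/6 mice were profiled by RNA sequencing on day 5 in 2 groups of 4 libraries, DSS and DSS_CA. The comparison asked how cholic acid altered gene expression in crypts of mice with DSS colitis. Total counts were 13499332, 17973196, 15945309 and 17724053 in DSS 1 to 4 and 14719976, 13730975, 13334012 and 15953432 in DSS_CA 1 to 4. The labels named no gut segment. Genes of small-intestinal absorption were abundant, with the lipoprotein gene Apoa4 at 19330 ± 12150 CPM and the sucrase-isomaltase gene Sis at 3766 ± 2178 CPM in DSS (SD, n = 4). Of colon-enriched genes, the 4 DSS libraries together held 2 counts of Hoxb13, and the 4 DSS_CA libraries held 0; a sum of 0 counts leaves room for up to 3.

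The libraries also differed along an axis that the groups did not follow. The mean length of a counted gene was 2234, 1423, 1448 and 1719 bases in DSS 1 to 4, and 2412, 2007, 1445 and 2019 bases in DSS_CA 1 to 4. It is the harmonic mean of gene length weighted by counts. Abundant short genes lower it, so it also reflects the composition of a library. The first principal component of log2 CPM held 50.9% of the variance and ranked the libraries much as this length did, with DSS 2, DSS 3 and DSS_CA 3 at one end. Mitochondrially encoded transcripts took between 9.72% (DSS_CA 1) and 27.7% (DSS 2) of the counts.

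**Figure D1:**
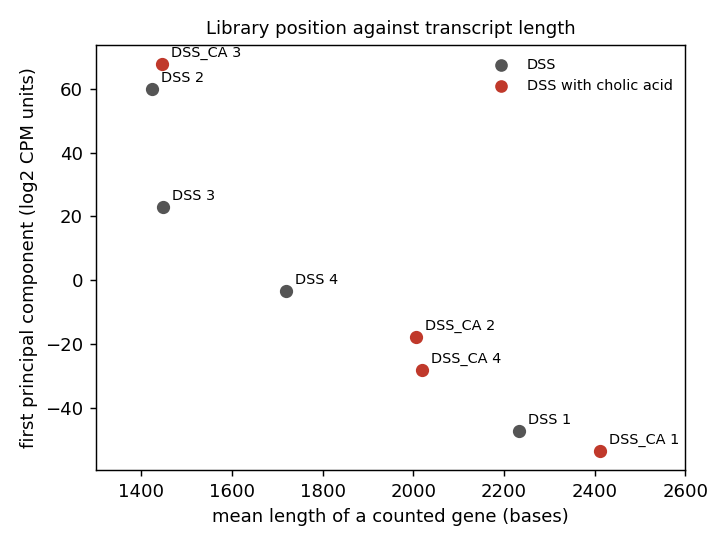
Position of each of the 8 libraries on the first principal component of log2 CPM (vertical axis) against the mean length of a counted gene in bases (horizontal axis), DSS in grey and DSS_CA in red. The length is a harmonic mean weighted by counts. DSS 2, DSS 3 and DSS_CA 3, with means of 1423, 1448 and 1445 bases, have the 3 highest positions, so both groups spread along the component.

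Cholic acid went with lower transcripts of lymphocytes and of interferon-inducible and antigen-presenting genes. Among single genes, 4 were higher and 9 lower in DSS_CA. Those with the largest falls were Mbl2, which encodes a mannose-binding lectin (11.3-fold lower, log2 fold change -3.49, SE 0.467, adjusted p = 0.0149), and Dio1, a thyroid hormone deiodinase (10.6-fold lower, -3.40, SE 0.356, adjusted p = 0.00293). Apol9b and Apol9a, near-identical genes of the apolipoprotein L family, fell 9.65-fold and 6.89-fold, from 59.9 ± 13.1 to 6.20 ± 1.22 CPM and from 59.6 ± 8.62 to 8.65 ± 0.731 CPM (adjusted p = 0.00193 for both). Nt5e, the ecto-nucleotidase CD73, fell 8.14-fold from 58.5 ± 32.1 to 7.18 ± 0.696 CPM (adjusted p = 0.0117), and the transmembrane gene Tmem140 fell 6.63-fold from 25.6 ± 5.25 to 3.85 ± 0.334 CPM (adjusted p = 0.00293).

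Of the other named genes that fell, Ccl5, a chemokine made by T cells among others, fell 3.92-fold from 116 ± 21.1 to 29.6 ± 10.1 CPM (adjusted p = 0.0477). Itgae, the integrin subunit CD103 that retains T cells in the epithelium, fell 3.72-fold from 40.1 ± 8.89 to 10.8 ± 2.42 CPM (adjusted p = 0.0380). The gene outside the naming rule, 2010109I03Rik, was 5.24-fold lower (adjusted p = 0.0105) and is named here because it completes the count of 9.

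The 4 genes that rose were led by Tcf23, a basic helix-loop-helix factor (11-fold, log2 fold change 3.46, SE 0.501, adjusted p = 0.0270), which was low in DSS at 1.66 ± 0.812 CPM and reached 18.3 ± 7.77 CPM. Tm4sf4, a tetraspan membrane protein of the gut epithelium, rose 9.23-fold from 53.9 ± 22.4 to 498 ± 273 CPM (adjusted p = 0.0380). Psat1, an enzyme of serine synthesis, rose 5.59-fold from 9.84 ± 4.46 to 55.0 ± 13.6 CPM (adjusted p = 0.0285). Akr1b8, an aldo-keto reductase, rose 4.65-fold from 4.47 ± 1.63 to 20.8 ± 1.58 CPM (adjusted p = 0.0285).

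**Figure D2:**
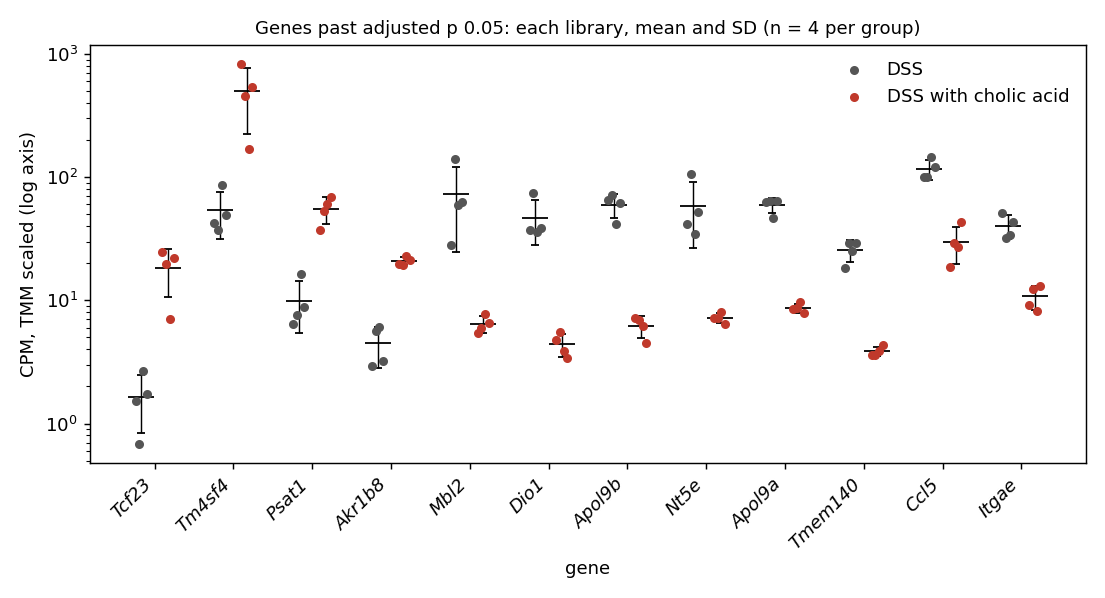
CPM after TMM scaling on a log axis for 12 of the 13 genes past the threshold, with each library as a point (DSS grey, DSS_CA red) and the mean and SD of the 4 libraries of a group as bars. The groups do not overlap for any of the 12 genes, and Tm4sf4 ranges from 169 to 833 CPM in DSS_CA against at most 86.7 CPM in DSS.

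Of the genes that rose, Tcf23 (ENSMUSG00000006642) lies on chromosome 5 from 30968662 to 30977018, Tm4sf4 (ENSMUSG00000027801) on chromosome 3 from 57425314 to 57441677, Psat1 (ENSMUSG00000024640) on chromosome 19 from 15904678 to 15947337 and Akr1b8 (ENSMUSG00000029762) on chromosome 6 from 34354119 to 34368463. Of those that fell, Mbl2 (ENSMUSG00000024863) lies on chromosome 19 from 30232928 to 30239685, Dio1 (ENSMUSG00000034785) on chromosome 4 from 107291465 to 107307169, Nt5e (ENSMUSG00000032420) on chromosome 9 from 88327197 to 88372092 and Tmem140 (ENSMUSG00000057137) on chromosome 6 from 34863146 to 34874946. Apol9b (ENSMUSG00000068246) and Apol9a (ENSMUSG00000057346) lie on chromosome 15 from 77729121 to 77736381 and from 77403789 to 77411080. Ccl5 (ENSMUSG00000035042) and Itgae (ENSMUSG00000005947) lie on chromosome 11 from 83525778 to 83530518 and from 73090583 to 73147446. All 12 are protein-coding genes, and counts were summed per gene.

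The 13 genes were found among 9913 tested with edgeR. At an unadjusted p below 0.05 there were 775 genes against 496 by chance, and the groups did not overlap in 600 genes (6.05%, against 2.86% by chance). A further 17 genes had an adjusted p between 0.05 and 0.06. The count depended on single libraries: 0 genes were higher and 7 lower without DSS 1, DSS 2 or DSS 4, 0 and 4 without DSS_CA 2 or DSS_CA 4, 3 and 7 without DSS_CA 1, 11 and 25 without DSS 3, and 19 and 65 without DSS_CA 3. In the 5 fits with 0 higher genes, edgeR gave 504 to 845 genes at an unadjusted p below 0.05. Without DSS 2, DSS 3 and DSS_CA 3, the libraries of shortest counted genes, 234 genes were higher and 421 lower, with all 13 genes among them. That fit set only DSS 1 and DSS 4 against DSS_CA 1, DSS_CA 2 and DSS_CA 4. The main fit used the same libraries, so the 13 genes gain no independent support from it.

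Transcripts of T and NK cells fell together in DSS_CA. All 11 measured members were below 0, with a mean log2 fold change of -1.90 (camera adjusted p = 1.0e-28, and adjusted p = 0.000712 with an estimated correlation). Over all genes only Itgae passed, and adjusted over the list alone 10 of the 11 members were lower. The T cell genes Cd8a (-1.57, SE 0.270) and Lck (-1.87, SE 0.329) and the cytotoxic granule gene Nkg7 (-1.92, SE 0.337) each had an adjusted p of 0.0502 over all genes. Granzyme B (Gzmb) was at 263 ± 141 CPM in DSS and 65.6 ± 57.7 CPM in DSS_CA.

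Genes of the interferon response fell as a group. The mean over 18 measured members was -1.26 (camera adjusted p = 6.31e-20, and adjusted p = 0.0094 with an estimated correlation), and all 18 were below 0. None passed over all genes, whereas 17 were lower when adjusted over the list alone. The guanylate-binding gene Gbp2 was at 7.47 and 2.08 CPM in DSS and DSS_CA (log2 fold change -1.84, SE 0.385), and the transcription factor gene Irf7 at 79.8 and 35.7 CPM (-1.16, SE 0.261).

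MHC class II genes, which present antigen to helper T cells, fell as well. Their mean was -1.32 over 7 measured members, all below 0 (camera adjusted p = 2.5e-12, and adjusted p = 0.0151 with an estimated correlation). None passed over all genes and all 7 were lower when adjusted over the list alone. H2-Aa was at 535 and 187 CPM (log2 fold change -1.52, SE 0.313) and H2-Eb1 at 225 and 91.7 CPM (-1.29, SE 0.287). The B and plasma cell list had 4 measured members, too few to test, with a mean of -1.49. Among them Igkc (-1.90, SE 0.385) and Ighm (-1.76, SE 0.398), the immunoglobulin kappa and mu constant regions, had adjusted p-values of 0.0806 and 0.111, and 3 of the 4 were lower when adjusted over the list alone.

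**Figure D3:**
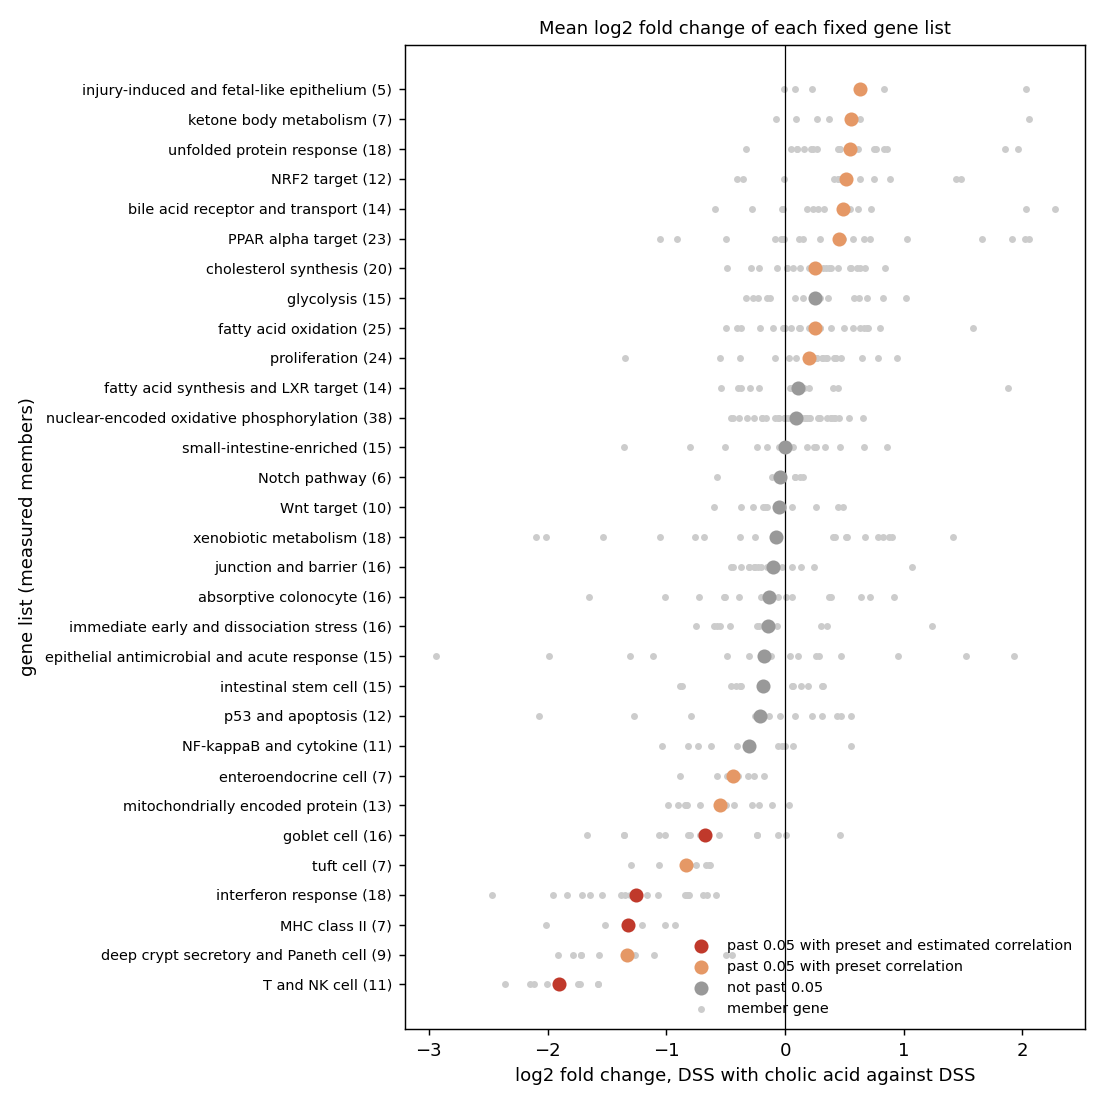
Mean log2 fold change (DSS_CA against DSS, horizontal axis) of each tested gene list as a large point and of its members as small grey points, with the number of measured members in brackets. Red lists were past an adjusted p of 0.05 with both a preset and an estimated correlation between genes, and these were T and NK cell (-1.90), MHC class II (-1.32), interferon response (-1.26) and goblet cell (-0.67).

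Markers of secretory epithelial cells were lower in DSS_CA. The Paneth and deep crypt secretory list fell with a mean of -1.33 over 9 measured members, all below 0 (camera adjusted p = 3.98e-07, but adjusted p = 0.172 with an estimated correlation). The groups overlapped in the mean log2 CPM of this list, at 6.90, 9.25, 9.24 and 8.39 in DSS 1 to 4 and 6.41, 7.28, 8.11 and 7.15 in DSS_CA 1 to 4, and the libraries of shortest counted genes were the highest of their groups. With a median gene length of 1068 bases, this list can itself lower that length where its genes are abundant. Its member with the smallest p was Nupr1, a stress-induced chromatin protein not restricted to Paneth cells (-1.91, SE 0.439), followed by Mmp7, the protease that activates Paneth cell defensins (339 and 141 CPM, -1.26, SE 0.435). No member passed over all genes, and 3 were lower when adjusted over the list alone. The defensin Defa24 was at 8361 ± 5535 and 2429 ± 1894 CPM, with reads that related defensins can share.

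Goblet cell markers fell with a mean of -0.67 over 16 members, of which 14 were below 0 (camera adjusted p = 0.000102, and adjusted p = 0.0305 with an estimated correlation). The goblet cell protein gene Clca1 was at 1219 and 476 CPM (-1.36, SE 0.363), and the mucin gene Muc2 had a log2 fold change of -1.06 (SE 0.494, adjusted p = 0.651). No member passed over all genes and 1 was lower when adjusted over the list alone. Tuft cell markers fell with a mean of -0.83 over 7 members, all below 0 (camera adjusted p = 7.06e-05, but adjusted p = 0.0642 with an estimated correlation). Over all genes 0 of them passed and 1 did when adjusted over the list alone. The leukotriene synthesis gene Alox5ap was at -0.80 (SE 0.373).

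Enteroendocrine markers fell with a mean of -0.44 over 7 members, all below 0 (camera adjusted p = 0.0230, but adjusted p = 0.172 with an estimated correlation). No member passed over all genes or when adjusted over the list alone, and the hormone gene Sst was at -0.88 (SE 0.367) and Chgb at -0.57 (SE 0.355). With each library left out, Sst ranged from -1.08 to -0.60 and Chgb from -0.80 to -0.22. The call of the list ended without DSS 3 (camera adjusted p = 0.0871) or DSS_CA 3 (0.191), with the gene length offset (0.163) and without the 3 libraries of shortest counted genes (0.289). With no filter the mean of the list turned to 0.12.

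Genes of the antioxidant NRF2 response and of the unfolded protein response rose as groups. The NRF2 list had a mean of 0.52 over 12 members, 9 of them above 0 (camera adjusted p = 8.61e-05, but adjusted p = 0.151 with an estimated correlation). None passed over all genes and 3 were higher when adjusted over the list alone, among them Gclc, the catalytic subunit for glutathione synthesis (36.7 and 102 CPM, 1.48, SE 0.262, adjusted p = 0.0502), and the malic enzyme gene Me1 (1.44, SE 0.296, adjusted p = 0.0820). The unfolded protein response list had a mean of 0.54, with 17 of 18 members above 0 (camera adjusted p = 0.000168, but adjusted p = 0.0873 with an estimated correlation). Asns, asparagine synthetase, was the 1 member higher when adjusted over the list alone (27.4 and 98.8 CPM, 1.85, SE 0.324, adjusted p = 0.0502 over all genes), and none passed over all genes. The chaperone-related gene Creld2 was at 0.83 (SE 0.271).

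Targets of the fatty acid receptor PPAR alpha rose with a mean of 0.45 over 23 members, 15 of them above 0 (camera adjusted p = 0.000993, but adjusted p = 0.172 with an estimated correlation). Over all genes 0 passed, and 4 were higher when adjusted over the list alone. Among these were the acyl-CoA thioesterases Acot2 (1.66, SE 0.384) and Acot1 (2.02, SE 0.496) and the fatty acid hydroxylase Cyp4a10 (1.91). Ppara itself was at 0.72 (SE 0.353, adjusted p = 0.692), Cpt1a at 0.67 and Pdk4 at 0.49, which turned to -0.31 without DSS_CA 3.

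Fatty acid oxidation genes rose with a mean of 0.25, with 16 of 25 members above 0 (camera adjusted p = 0.0114, but adjusted p = 0.283 with an estimated correlation). Acadl, a long-chain acyl-CoA dehydrogenase, was the 1 member higher when adjusted over the list alone (95.5 and 286 CPM, 1.58, SE 0.323), none passed over all genes, and Eci2 was at 0.80 (SE 0.272). Ketone body genes rose with a mean of 0.55 over 7 members (camera adjusted p = 0.0115, but adjusted p = 0.106 with an estimated correlation). Of these, 6 were above 0, 0 passed over all genes and 1 was higher when adjusted over the list alone, with the transporter gene Slc16a1 at 0.53 (SE 0.278). Without DSS 1 both calls ended, at adjusted p = 0.125 for fatty acid oxidation and 0.0522 for ketone bodies.

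The bile acid receptor and transport list rose with a mean of 0.49 over 14 members, 10 of them above 0 (camera adjusted p = 0.0203, but adjusted p = 0.112 with an estimated correlation). Fgf15, the hormone gene that the bile acid receptor FXR induces in the ileum, was at 13.2 and 63.5 CPM (2.27, SE 0.530, adjusted p = 0.125). Nr0b2, another FXR target, was at 1.51 and 6.20 CPM (2.03, SE 0.471, adjusted p = 0.119). Both were higher when adjusted over the list alone, and no member passed over all genes. The call ended without DSS 2 (adjusted p = 0.0732), DSS 3 (0.0515) or DSS_CA 3 (0.153). Nr1h4, which encodes FXR, was at 0.73 (SE 0.487, adjusted p = 0.869) and the bile acid transporter genes Slc51a and Slc51b at 0.50 and 0.62. Without DSS_CA 3, Slc51b turned to -1.04 and Nr1h4 to -0.00735. The bile acid receptor gene Gpbar1 had 2 counts in DSS and 1 in DSS_CA, too few for a difference to be detectable at this depth.

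Cholesterol synthesis genes rose with a mean of 0.25, with 16 of 20 members above 0 and none past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.0268, but adjusted p = 0.460 with an estimated correlation). The call ended without DSS 2 (adjusted p = 0.157), DSS 3 (0.140), DSS_CA 1 (0.0663) or DSS_CA 3 (0.0959), and without the 3 libraries of shortest counted genes (0.874). Mitochondrially encoded genes fell with a mean of -0.55, with 12 of 13 members below 0, 0 past the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 0.000993, but adjusted p = 0.447 with an estimated correlation). The examples mt-Nd4l and mt-Nd4 were at -0.98 (SE 0.449) and -0.90 (SE 0.466), and the call ended without DSS 2 (adjusted p = 0.0732). Nuclear genes of oxidative phosphorylation had a mean of 0.09 (camera adjusted p = 0.250), with 0 of 38 members past the threshold over all genes or adjusted over the list alone, Ndufa10 at 0.54 and Ndufb5 at 0.45; this list passed without DSS 3 (adjusted p = 0.00439) or DSS_CA 1 (0.0445).

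Proliferation genes rose slightly, with a mean of 0.20 and 20 of 24 members above 0 (camera adjusted p = 0.0285, but adjusted p = 0.172 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, was at 0.94 (SE 0.323), whereas Cenpf was at -1.35 (SE 0.632), and at -0.55 without DSS 2, and Mki67 at -0.55 (SE 0.433, adjusted p = 0.911). No member passed over all genes or adjusted over the list alone. The call ended without DSS 1 (adjusted p = 0.0717), DSS 3 (0.0939) or DSS_CA 1 (0.109).

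The injury-induced and fetal-like list rose with a mean of 0.63 (camera adjusted p = 0.00606, but adjusted p = 0.0900 with an estimated correlation), with 5 of its 19 members measured and 4 of these above 0. It rested on the growth factor Areg (6.37 and 26.0 CPM, 2.03, SE 0.374, adjusted p = 0.0605), the 1 member higher when adjusted over the list alone, and on the related Ereg (0.83, SE 0.394), with 0 members past the threshold over all genes. With no filter the mean turned to -0.29. The injury marker Clu fell below the expression filter, with 114 and 61 counts (-0.87, adjusted p = 0.685 in a fit with no filter).

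Stem cell genes had a mean of -0.19 (camera adjusted p = 0.293, and 0.0435 without DSS_CA 1), with 0 of 15 members past the threshold over all genes or adjusted over the list alone. The stem cell genes Olfm4 and Ascl2 were at -0.88 (SE 0.50, adjusted p = 0.764, and -0.42 without DSS 2) and -0.37, and the ion transporter gene Slc12a2 at -0.87 (SE 0.399). Lgr5, the marker of crypt base stem cells, fell below the filter, with 469 counts in DSS and 175 in DSS_CA, and in a fit with no filter its log2 fold change was -1.44 (SE 0.467, adjusted p = 0.233). Wnt targets had a mean of -0.05, to which the test gave the opposite sign (camera adjusted p = 0.993), with Cd44 at 0.49 and Myc at 0.45. Notch pathway genes had a mean of -0.04 and a median of 0.08 (camera adjusted p = 0.817), with Dll4 at -0.57 and Hes1 at 0.13. In both lists 0 members passed over all genes or adjusted over the list alone.

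Other epithelial lists did not pass. Absorptive colonocyte genes had a mean of -0.13 (camera adjusted p = 0.493), with Ceacam20 at -1.65 (SE 0.370) and lower when adjusted over the list alone, Ppargc1a at -1.01 (SE 0.346) and Krt20 at -0.20, which was 0.05 without DSS 2. Small-intestine genes had a mean of -0.0027 against a median of 0.07 and a test in the upward direction (camera adjusted p = 0.914), with Apoc3 at -1.35 (SE 0.392) and Mttp at 0.86 (SE 0.306) and 0 of 15 members past the threshold in either adjustment. Junction and barrier genes had a mean of -0.10 (camera adjusted p = 0.542), with the claudin Cldn2 at 1.07 (SE 0.275) and higher when adjusted over the list alone, and Ocln at -0.46. Antimicrobial and acute response genes had a mean of -0.18 and a median of 0.04 (camera adjusted p = 0.416, and a mean of -0.84 with adjusted p = 0.0268 without DSS_CA 3). Adjusted over the list alone, 2 of its members were higher and 2 lower, with the metallothionein Mt2 at 1.93 (SE 0.349, adjusted p = 0.0564) and Ido1, a tryptophan-degrading enzyme that interferon induces, at -2.94 (SE 0.632, adjusted p = 0.0990). Reg3g was at 0.29 with DSS_CA 3 and at -1.47 without it, and Lcn2 fell below the filter with 29 and 50 counts.

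Of the other metabolic and stress lists, glycolysis had a mean of 0.25 (camera adjusted p = 0.0619), with Slc2a1 at 1.02 and Pgam1 at 0.82; it passed without DSS 3 (adjusted p = 0.0203), DSS_CA 3 (0.0178) or DSS_CA 4 (0.0383). Fatty acid synthesis and LXR targets had a mean of 0.11 (camera adjusted p = 0.493), with the desaturase Scd1 at 1.88 (SE 0.469) and higher when adjusted over the list alone, and Lpcat3 at 0.40. Xenobiotic metabolism had a mean of -0.08 against a median of 0.41 and a test in the upward direction (camera adjusted p = 0.733). Adjusted over the list alone 1 member was higher, Gsta1 (1.42, SE 0.378), and 2 were lower, among them Cyp2c55 (-2.10, SE 0.573). NF-kappaB and cytokine genes had a mean of -0.30 (camera adjusted p = 0.10), with Relb at -0.73 and Nfkbiz at -0.63. The p53 and apoptosis list had a mean of -0.21 and a median of 0.02 (camera adjusted p = 0.493), with Fas (-1.28, SE 0.368) and Trp53inp1 (-2.07, SE 0.605) lower when adjusted over the list alone. Immediate early and dissociation stress genes had a mean of -0.14 (camera adjusted p = 0.254), with Egr1 at 1.24 and Atf3 at -0.75, and passed without DSS_CA 1 (-0.28, adjusted p = 0.0485). In these 6 lists no member passed over all genes.

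Markers of other cell types were scarce. None of the fibroblast and smooth muscle or enteric glia and neuron genes reached the filter, and 1 gene each was measured for neutrophils (Cd177, -0.78), endothelium (Lyve1, 0.37, and -0.33 without DSS_CA 3) and erythroid cells (Hbb-bs, 0.19). The macrophage and dendritic cell list had 3 measured members, with Lyz2 at -1.60 (SE 0.623). Of its members below the filter, most had fewer counts in DSS_CA, such as Itgax (271 and 68), C1qa (73 and 21), C1qb (68 and 22) and Aif1 (48 and 2), whereas Cd68 had 63 and 56 and Mrc1 129 and 211; these counts were not tested. The colon-enriched list had 2, with Slc37a2 at 0.65 and B4galnt2 at -0.17, and none of the measured members of these lists passed over all genes or adjusted over its list alone.

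The composition of the libraries was compared with exact two-sided permutation tests, and no measure passed. With 4 against 4 libraries a lone difference could not have passed after adjustment over the 5 planned measures, so these tests leave differences open. Mitochondrial genes took 20.4 ± 5.10% of counts in DSS and 14.4 ± 4.48% in DSS_CA (SD, n = 4, exact p = 0.143, adjusted p = 0.357), and the 10 top genes took 23.7 ± 5.88% and 17.7 ± 6.91% (exact p = 0.257, adjusted p = 0.429). Ribosomal protein genes took 2.31% and 2.46% (exact p = 0.857, adjusted p = 0.971), and haemoglobin genes 0.000421% and 0.00063% (exact p = 0.114, adjusted p = 0.357). Genes at FPKM 1 or more numbered 9518 and 9562 (exact p = 0.971, adjusted p = 0.971). The mean length of a counted gene, a measure added after the data were seen, was 1706 ± 377 and 1971 ± 398 bases (exact p = 0.371).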

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

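The tests with a gene length offset on the immune, secretory and enteroendocrine lists, the counts without 3 libraries and the test for fewer crypts were chosen only after the results were seen.

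In 206 groups of 4 libraries, 18 had 1 library far outside the range of the other 3 by Dixon's ratio, or 8.74%, where chance gives about 1 in 20. Of these, 10 concerned DSS_CA 3. Its CPM were above the other 3 libraries for Reg3g (4038, others 244.6 to 518.8), Slc51b (1055, others 59.8 to 143.5), Krt20 (3996, others 1701 to 2039), Lyve1 (11.86, others 2.889 to 3.909) and Slc16a1 (140.2, others 92.6 to 100). They were below the others for Olfm4 (158.7, others 460 to 506.2), Ceacam20 (21.37, others 32 to 33.33), Hes1 (5.01, others 13.58 to 14.39) and Cd177 (2.658, others 6.656 to 7.276). It also had the fewest genes at FPKM 1 or more, 8582 against 9833 to 9983.

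DSS 2 had higher CPM than the other 3 DSS libraries for Dio1 (74.14, others 36.13 to 38.39), Ido1 (101.8, others 37.49 to 43.28) and Ighm (10.07, others 4.622 to 5.477). DSS 3 had lower Apol9a (46.71 CPM, others 62.62 to 64.54), higher Irf7 (102.5 CPM, others 70.29 to 73.66) and a higher haemoglobin share (0.0006961%, others 0.000306% to 0.0003554%). DSS_CA 1 had higher CPM for Slc12a2 (120.5, others 92 to 94.41) and Slc2a1 (30.69, others 16.46 to 18.16).

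Among the 35 splits of the 8 libraries into 4 and 4, 2 gave at least as many genes as the real split with its 13, so chance could not be excluded by that count. The other split, DSS 1 with DSS_CA 1, 2 and 4 against DSS 2, 3 and 4 with DSS_CA 3, gave 1099 genes. It followed the first principal component and the length of counted genes, and so points to a structure of the samples. The 17 gene lists were exceeded or matched in no other split (1 of 35, highest other 15). That is the smallest share that 35 splits can give, and mixed splits reached 15 and 14 lists. The real split thus ranked first by a small lead, which does not exclude chance for the count of lists.

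The libraries DSS 2, DSS 3 and DSS_CA 3 stood apart on the first component, which held 50.9% of the variance. Across genes, which are not independent replicates, the loadings of this component correlated with gene length at a Spearman coefficient of -0.321. Removal of the length trend of each library lowered the variance of the component by 12% and left it with 50.3% of the variance that remained. A trend with gene length is thus a candidate source of part of this component, and most of it stays unexplained. Differences in RNA quality or in the part of the crypts collected were not tested, and no biological explanation was tested because the component crosses the groups.

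The T and NK cell, interferon response and MHC class II lists were lower in DSS_CA. The trend with gene length argued against itself as the whole cause, since the mean over their 36 members was -1.47 (SD 0.509) without and -1.45 (SD 0.50) with the length offset, and all 3 lists stayed past the threshold. Fewer lymphocytes in the preparations could lower the T and NK cell list directly, and the data cannot tell whether they also account for the other lists. The deviations of the interferon list from the group means correlated with those of the T and NK cell list at r = 0.503 over 8 libraries (exact permutation p = 0.304, adjusted p = 0.608; rho = 0.286, p = 0.609, adjusted p = 0.609), and at -0.205 without DSS_CA 1 and DSS_CA 3. Those of MHC class II against B and plasma cells gave r = 0.0173 (exact permutation p = 0.970, adjusted p = 0.970; rho = -0.310, p = 0.512, adjusted p = 0.609), and -0.447 without DSS_CA 1 and DSS 1, the 2 relations computed over 576 permutations each leaving intervals too wide to decide; fewer macrophages or dendritic cells, which also carry MHC class II, were not tested, and an effect of cholic acid on the immune cells or on the epithelium stays open.

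The goblet, Paneth and tuft cell lists were also lower in DSS_CA. With the length offset the mean over their 32 members was -0.811 (SD 0.534) against -0.894 (SD 0.571) without it, and all 3 lists stayed past the threshold, which argues against the length trend as the whole cause, although the Paneth list moved from -1.33 to -1.15, and to -0.89 without the 3 libraries of shortest counted genes (goblet from -0.67 to -0.83 there), so part of its fall may follow that trend. The enteroendocrine list was taken out of this pattern after its call was seen to end under the offset, where its mean moved from -0.441 (SD 0.236) to -0.293 (SD 0.242, adjusted p = 0.163) and the length trend cannot be told apart from a group effect; over all 4 lists the mean with the offset was -0.718. A lower share of crypts in the preparations would lower proliferation genes too, if proliferation within the crypts were equal in both groups. Their mean stayed above 0 with each library left out (lowest 0.139). Whether proliferation within the crypts was equal was not tested, so this result cannot exclude a lower share of crypts. A loss from the crypt base alone was not tested and may be technical or an effect of cholic acid. The stem cell list as a whole did not pass (mean -0.19, camera adjusted p = 0.293). Of its 15 measured members 9 were below 0, among them Olfm4 at -0.88 and Slc12a2 at -0.87. The 6 above 0 included Smoc2 at 0.14, Ephb2 at 0.31 and Lrig1 at 0.32. The crypt base marker Lgr5, below the filter, had 469 counts in DSS and 175 in DSS_CA. In an edgeR fit with no filter Lgr5 was at -1.44 (adjusted p = 0.233).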

How the results depend on the processing

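The tests with the filterByExpr filter, with the gene length offset and without the 3 libraries of shortest counted genes (DSS 2, DSS 3, DSS_CA 3) were chosen after the data were seen. Of the 17 called lists, 9 kept their direction and call in every setting that tested them other than the estimated correlation, and with each library left out: T and NK cell, interferon, MHC class II, Paneth, goblet, tuft, NRF2, PPAR alpha and unfolded protein response. The 13 called genes kept their sign in every setting that tested them (9 of them under the stricter filter). Except where a setting used fewer libraries or genes, the cause of the changes below was not tested. The depth limits genes of few counts, such as Gpbar1 and Lcn2.

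The count of 4 higher and 9 lower genes was 13 and 40, 12 and 30, and 13 and 39 with limma on log2(FPKM) at pseudocounts of 1, 0.1 and 0.5. It was 18 and 61 with no filter, 7 and 20 with DESeq2 size factors, 14 and 23 with quantile normalization, 11 and 23 with limma voom, 51 and 169 with the DESeq2 Wald test, and 17 and 43 with the length offset. Robust edgeR gave 18 lower genes. Library quality weights gave 2213 higher and 2100 lower genes, with a weight of 14.4 on DSS 4 against 0.173 to 3.85 on the others. Without the 3 libraries 234 genes were higher and 421 lower. With each library left out, 0 to 19 genes were higher and 4 to 65 lower. Scaling by library size alone left 2 higher genes and moved the median of all genes by 0.188, so the list values under it are relative to that shift.

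Higher lists numbered 5 with the stricter filter, and 0 higher and 4 lower lists passed with an estimated correlation. There bile acid (0.487), cholesterol (0.255), Paneth (-1.33), enteroendocrine (-0.441), fatty acid oxidation (0.250), injury (0.634), ketone body (0.554), mitochondrial (-0.551), NRF2 (0.516), PPAR alpha (0.454), proliferation (0.201), tuft (-0.835) and unfolded protein response (0.545) kept their mean and lost their call. The estimates for bile acid (-0.019), injury (-0.0341) and ketone body (-0.0535) lay below the preset 0.01. Correlation between genes therefore does not account for the loss of these calls. Calls also ended for bile acid (0.325), cholesterol (0.168) and proliferation (0.195) with the stricter filter, for cholesterol (0.407), enteroendocrine (-0.209) and proliferation (0.413) with library size only, and for mitochondrial genes with quantile normalization (-0.212). They ended for bile acid (0.287), cholesterol (0.0880) and enteroendocrine (-0.386) with quality weights, and for cholesterol (0.243), enteroendocrine (-0.293) and proliferation (0.190) with the length offset. Without the 3 libraries bile acid (0.277), cholesterol (0.0272) and enteroendocrine (-0.317) lost theirs. The enteroendocrine call ended with nuclear library sizes (-0.319) and filterByExpr (-0.0876).

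Lists gained a call as follows. Glycolysis passed at pseudocounts of 1 (0.227) and 0.5 (0.237), with no filter (0.267), quantile normalization (0.325), quality weights (0.308) and without the 3 libraries (0.368). Oxidative phosphorylation passed with no filter (0.151), quality weights (0.151) and without the 3 libraries (0.296). NF-kappaB passed with no filter (-0.625), the stricter filter (-0.493), quality weights (-0.396) and filterByExpr (-0.429). Antimicrobial genes passed with quality weights (-0.803) and without the 3 libraries (-0.851), and immediate early genes with the stricter filter (-0.289).

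Signs turned under library size only for absorptive colonocyte (0.0391), immediate early (0.0692), stem cell (0.0195), junction (0.103), Notch (0.181), small-intestine (0.168), Wnt (0.119), xenobiotic (0.161) and B4galnt2 (0.0103). Nuclear library sizes moved the median of all genes by 0.0841, more than the values of the lists that turned there, so these turned with the common shift: Notch (0.0742), small-intestine (0.0689), Wnt (0.0210) and xenobiotic (0.0422). With no filter enteroendocrine (0.123), injury (-0.288) and small-intestine (0.0640) turned. Small-intestine also turned with quantile normalization (0.179), filterByExpr (0.0353) and the length offset (0.0274), and fatty acid synthesis with the stricter filter (-0.0820) and without the 3 libraries (-0.0424), where xenobiotic genes passed upward (0.191). Hes1 (-0.0220), Slc51b (-0.117) and Reg3g (-0.652) turned at a pseudocount of 0.1, and Hes1 (-0.00702), Slc51b (-0.0874), Reg3g (-0.584) and Krt20 (0.0683) with quantile normalization. The difference in ribosomal protein share turned to -0.00165 once mitochondrial genes and small RNAs were left out.

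With each library left out the means ranged from 0.279 to 0.575 for bile acid, 0.184 to 0.360 for cholesterol, -0.538 to -0.369 for enteroendocrine, 0.166 to 0.398 for fatty acid oxidation, 0.478 to 0.686 for ketone body, -1.04 to -0.243 for mitochondrial and 0.139 to 0.230 for proliferation genes. They ranged from -0.835 to -0.0647 for antimicrobial, 0.145 to 0.401 for glycolysis, -0.276 to -0.0247 for immediate early, -0.334 to -0.00940 for stem cell, -0.221 to 0.178 for Notch, -0.135 to 0.319 for oxidative phosphorylation, -0.0830 to 0.0483 for small-intestine, -0.212 to 0.211 for Wnt and -0.225 to 0.120 for xenobiotic genes. Genes ranged from -0.303 to 0.0818 for B4galnt2, -0.331 to 0.785 for Lyve1, -0.0638 to 0.673 for Hbb-bs, -1.04 to 0.970 for Slc51b, -0.312 to 0.782 for Pdk4, -1.47 to 0.633 for Reg3g, -0.563 to 0.0477 for Krt20 and -0.00735 to 0.986 for Nr1h4. The ribosomal share difference ranged from -0.246 to 0.619 points, and that of genes at FPKM 1 or more from -189 to 372.

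The labels do not say whether the replicate numbers pair the samples, and the correlations did not settle it. Deviations from the group means correlated at 0.752, -0.344, 0.105 and 0.197 for libraries of the same number, and DSS 2 correlated best with DSS_CA 3 (0.734). With the replicate block 14 genes were higher and 51 lower, Slc51b turned to -0.105 and Reg3g to -0.664, and the block changed no list call.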

Other observations

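The enrichment over KEGG terms was chosen after the comparison of genes and lists was seen, as were the genes named here.

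Several KEGG terms of tRNA charging, ribosome assembly, glycosylation and folate metabolism were higher in DSS_CA by small amounts at the preset correlation, and none of them at an estimated correlation. Of the 40 measured genes of aminoacyl-tRNA biosynthesis, 36 were above 0, with a mean log2 fold change of 0.47 (camera adjusted p = 2.43e-08, but adjusted p = 0.0860 with an estimated correlation). Among them Cars and Gars, which charge tRNA with cysteine and glycine, were at 1.06 (SE 0.253) and 1.10 (SE 0.304). The Ribosome term itself did not pass, with 82 of 124 genes above 0 (adjusted p = 0.176, and 0.998 with an estimated correlation). Ribosome biogenesis had 62 of 67 genes above 0 (adjusted p = 0.000358, but 0.117 with an estimated correlation) and N-glycan biosynthesis 35 of 40 (adjusted p = 0.000522, but 0.570). In the one-carbon pool by folate 10 of 12 genes were above 0 (adjusted p = 0.00261, but 0.519). Biosynthesis of amino acids (adjusted p = 0.000226, but 0.641) and glycine, serine and threonine metabolism (adjusted p = 0.00317, but 0.519) were higher at the preset correlation only. Single genes of amino acid metabolism, chosen after their values were seen, included the amino acid response factor Atf5 at 2.33 (SE 0.509), the cystathionine lyase gene Cth at 1.31 (SE 0.309), the mitochondrial folate enzymes Shmt2 at 1.21 (SE 0.401) and Mthfd2 at 1.20 (SE 0.271), beside Psat1, which passed over all genes, and Asns at 1.85. Atf5, Cth, Shmt2 and Mthfd2 had adjusted p-values of 0.102, 0.131, 0.358 and 0.115 in edgeR and so did not pass.

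Of 294 terms with 10 to 300 measured genes, 27 were higher and 33 lower. With an estimated correlation 0 higher and 2 lower terms remained, Primary immunodeficiency (adjusted p = 0.0286) and NOD-like receptor signaling (adjusted p = 0.0311). Of the 35 splits of the libraries, 9 gave at least 60 terms, the highest other 94, so chance could not be excluded for the count of terms.

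Apol7a and Apol10a, also of the apolipoprotein L family, had lower mean CPM in DSS_CA than in DSS. Neither passed the threshold, and the family was not tested as a group. Apol7a was at 125 ± 50.4 CPM in DSS and 28.8 ± 9.50 CPM in DSS_CA (-2.11, SE 0.360, adjusted p = 0.0502), and Apol10a at 706 ± 484 and 101 ± 44.1 CPM (-2.80, SE 0.525, adjusted p = 0.0654). The T cell receptor delta constant gene Trdc was at 15.8 ± 1.48 and 4.42 ± 1.88 CPM (-1.84, SE 0.353, adjusted p = 0.0683). Ddah1, an enzyme that degrades an inhibitor of nitric oxide synthesis, was at 6.81 ± 2.94 and 33.4 ± 8.75 CPM (2.29, SE 0.394, adjusted p = 0.0502).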
